A study of Rattus norvegicus with 4 samples.

How the data were processed

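Total RNA of 4 rat granulosa cell cultures, 2 with Runx2 siRNA and 2 with negative control siRNA, was labelled with biotin and measured on 1-colour expression arrays, 1 array per culture. The deposited values are array intensity, the MAS5 signal on a linear scale, with MAS5 named in the submitters' processing notes and its version not given in the sources used here. From the values themselves, the mean of each array's signal after trimming 2% at each end is about 500, so the arrays had been scaled to a common level, and no detection calls were used here. Scaling to a common mean sets total signal equal and would hide a change in total RNA per cell. The MAS5 signal subtracts mismatch probes, which makes dim probe sets variable, and this is why a constant and a filter on dim probe sets were used.

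The table held 31099 probe sets, of which 57 were array controls and were left out of the tests. Of the other 31042, the probe table pairs 20826 with 1 gene symbol, 436 with several and 9780 with none, and only probe sets with 1 symbol were named. Gene identifiers matched a current rat gene table (GRCr8 assembly, used for names only) for 20764 probe sets and did not for 68, and 0 symbols changed. The columns not tied to a sample numbered 0. Signals were tested as log2(signal + 16), a scale that understates the change of dim probe sets, and the lowest 40% by mean signal over the 4 arrays, below a signal of 78.6, were left out, which left 18625 probe sets, 14102 of them with 1 symbol, for 10017 genes. The authors' scaling was kept, and the median difference over all tested probe sets was 0.05.

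Groups and replicate numbers were taken from the sample titles, and the series description says that the cultures were separate. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), Runx2 siRNA against control siRNA, two-sided, over the 4 arrays without a term for replicate number, with 2 residual and 3.32 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A gene with several probe sets was represented in the lists by its brightest. The 21 gene lists were tested with camera at a correlation of 0.01 and with an estimated correlation, and with fry, and p was adjusted over the lists. With an estimated correlation camera rests on 2 residual degrees of freedom, so a list can hardly pass after adjustment over 21 lists. The estimate also comes from residuals that hold any difference between replicate numbers. Failing there after adjustment therefore decides little about a list. The lists that camera called at 0.01 also had an unadjusted camera p above 0.05 there, from 0.0961 to 0.360. The estimated correlation was 0.80 for the cholesterol list and 0.38 for the cell cycle list, above the 0.01 assumed. Where members vary together, camera p-values at 0.01 can be too small. Members were also adjusted over the list alone. A list of 5 genes was recalled from knowledge of the study and is not independent of these samples. List members and probe sets that are not named in the table or fell below the filter were not analysed here.

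Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule Runx2 is always named, followed by the 12 largest rises and the 12 largest falls with non-overlapping groups among probe sets with an adjusted p under 0.05. Predicted or numbered names and probe sets with several symbols are excluded, and each gene counts once. Missing places are filled from probe sets with an unadjusted p under 0.01 and no overlap, given as values, which was the case for all 24 here. From each list, up to 8 members past the threshold over the list alone and up to 4 others with the largest differences could be named.

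On simulated data with the real arrays' levels, 10 tables of 18625 probe sets with 200 changed in each, limma recovered 64.9% of 2-fold, 97.8% of 4-fold and 99.7% of 8-fold changes. It called 14.7 unchanged probe sets per table, and 4.69% of unchanged probe sets had an unadjusted p under 0.05. These simulations hold no shared difference between arrays of the same number. Their noise used each probe set's variance after shrinkage by limma, which spreads less than the raw variance, so recovery on the real arrays can be lower. There Cxcl3 and Slc51a differed more than 4-fold (log2 -2.67 and -2.38) and had adjusted p of 0.278 and 0.344 by limma. A lack of probe sets passing therefore does not show that such changes were absent. In 10 simulated tables the list test called 10 of 10 shifted lists of 22 members and 0 of 10 unshifted ones. With an estimated correlation it also called 10 shifted and 0 unshifted lists. These lists had members with independent noise and were judged at an unadjusted p under 0.05. They do not show how often the test calls an unshifted list whose members vary together.

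The alternatives were constants of 1 and 64, quantile and cyclic loess normalization, no filter and a filter at 60%, the replicate number as a term, other variance priors, each array left out in turn, the mean of a gene's probe sets, an estimated correlation and an adjusted threshold of 0.1. Leaving out 1 array leaves the replicate numbers unequal between the siRNA groups, so such a fit also holds part of any difference between numbers. A background of 1 probe set per gene and the count at an unadjusted p under 0.05 were added after seeing the data.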

Results

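Transcript levels were measured in granulosa cells, the steroid-producing cells that line the ovarian follicle. The cells came from immature female Sprague Dawley rats, 27 days old, given PMSG, a gonadotropin that makes follicles grow, 48 h before collection. They received 20 nM of an siRNA against Runx2 or 20 nM of a negative control siRNA and were then kept for 48 h with 10 µM forskolin, which activates adenylyl cyclase and so raises cAMP. Runx2 is a transcription factor best known from bone formation. Each group held 2 arrays, 1 per culture, and their small number limits the precision of every value. Median MAS5 signal was 141 and 153 on the Runx2 siRNA arrays and 129 and 137 on the control arrays, and array pairs correlated across probe sets at r = 0.949 to 0.980. The second Runx2 siRNA array stood apart in its spike-in transcripts, whose geometric mean signal was 1.72 times the mean of the control arrays, against 0.952 for the first. Its actin 3' to 5' signal ratio, a sign of RNA quality, was 1.71 against 1.42 to 1.45 on the other arrays, while its GAPDH ratio was 0.949 against 0.978 to 1.03, and its highest signal was 30500 against 18398 to 19702.

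The comparison asked which transcripts depend on the Runx2 that an agonist induces in these cells. The targeted gene itself was not analysed here, because the probe table used pairs 0 probe sets with Runx2, so the extent of the knockdown is not known from these values and the group names rest on the labels. Of the related genes, Runx1, a transcription factor of the same family, had a mean signal of 2156 ± 158 with Runx2 siRNA and 1293 ± 509 with control siRNA (SD, n = 2 arrays each). That is a log2 difference of 0.79 ± 0.27 (SE), and 1.11 ± 0.24 for a dimmer Runx1 probe set. Cbfb, the shared binding partner of the Runx proteins, differed by 0.12 ± 0.09, and its second probe set by -0.15 ± 0.15. None of the 4 measured members of the Runx list passed the test adjusted over the list alone, and the list did not pass either (adjusted p = 0.460).

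With Runx2 siRNA, transcripts for a prostaglandin D2 synthase and a collagenase fell, as judged by p-values adjusted over the list alone. Ptgds, the synthase, passed in the prostaglandin list, with a signal of 346 ± 25.3 with Runx2 siRNA against 948 ± 54.2 with control siRNA (SD, n = 2 each), a log2 difference of -1.41 ± 0.13 (SE). Mmp13, the collagenase, passed in the list of bone targets of Runx2 and in the matrix list, and lay at 112 ± 54.8 against 450 ± 89.6, a difference of -1.92 ± 0.34. Both also belong to a list of 5 genes recalled from knowledge of the study and probably chosen on these same samples. Its other members were Fabp6, a bile acid binding protein, at -2.35 ± 0.60, Abcb1a, a drug efflux pump, at -1.19 ± 0.25 with a second probe set at -0.55 ± 0.39, and Rgcc, a regulator of the cell cycle, at -0.97 ± 0.26. All 5 passed over the recalled list alone, which is not independent evidence, and Rgcc did not pass in the luteal list (adjusted p = 0.117). The recalled list had a median of -1.41 (adjusted p = 3.5e-07 by camera, adjusted p = 0.733 with an estimated correlation), and this too is not independent of the choice of its genes.

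In the other lists the genes that fell were Fosb and Egr2, both immediate early transcription factors, with log2 differences of -1.21 ± 0.12 and -0.97 ± 0.14, and Psat1, an enzyme of serine synthesis, with -1.07 ± 0.12 (SE, n = 2 arrays per group). Wnt4, a signalling ligand of granulosa cells, fell by 0.98 ± 0.13 and Igf1r, the receptor of insulin-like growth factor 1, fell by 0.64 ± 0.12. Spp1, the secreted phosphoprotein osteopontin, fell by 1.19 ± 0.22 and Adamts1, a protease that cuts versican, fell by 0.46 ± 0.10 in the matrix list (adjusted p = 0.0422 over the list) but did not pass in the ovulatory list (adjusted p = 0.0603). Igf1, the growth factor, rose from 2023 ± 78.5 to 3555 ± 237 (SD), a log2 difference of 0.81 ± 0.10, and Serpine2, an inhibitor of serine proteases, rose by 0.56 ± 0.11. Leaving the recalled list aside and counting genes once, 9 fell and 2 rose over the list alone, in 13 list memberships. Ptgds and Mmp13 are also in the recalled list and are still counted here through other lists. The count is therefore not free of genes probably chosen on these samples. Over all 18625 probe sets tested 0 passed. With the replicate number as a term 1512 passed, 610 higher and 902 lower, but the labels do not say that a number marks a shared culture. In the values, deviations of same-numbered arrays correlated at 0.548 across probe sets. The residual and SEs of the fit without that term therefore hold a difference between numbers, and its 0 does not show that no transcript changed. Without that term the lowest adjusted p over all by limma was 0.248, and 2225 probe sets had an unadjusted p under 0.05. Of these 1202 were higher and 1023 lower, where chance alone would give 931 in all. Dividing the arrays by replicate number gave 1354, of which 2 passed over all. The remaining division gave 41, but its residual holds both the siRNA and the number differences, so it is no baseline. After cyclic loess scaling the siRNA groups gave 876 higher and 1241 lower. Whichever array was left out, 7 of the 13 memberships were kept. Serpine2 and Adamts1 were not called without the second Runx2 siRNA array or without either control array, and Igf1r and Egr2 without either control array. Without the first control array 871 probe sets had an unadjusted p under 0.05, against 3596 without the first Runx2 siRNA array.

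**Figure D1:**
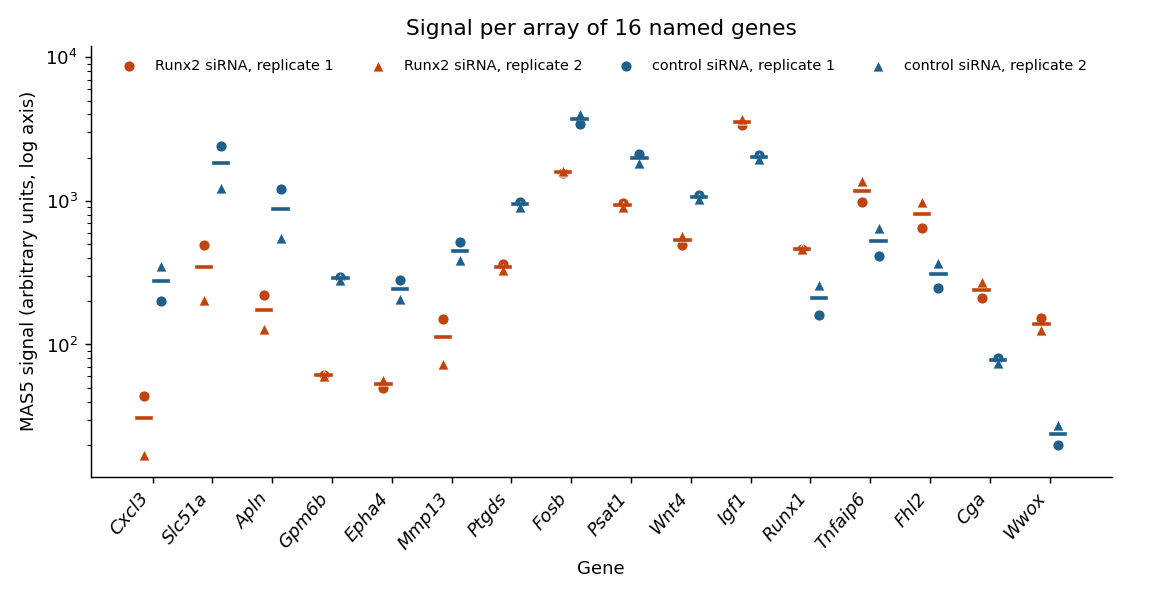
MAS5 signal in arbitrary units on a log axis for 16 named genes, 1 symbol per array (circles replicate 1, triangles replicate 2) with a bar at each group's mean. Runx2 siRNA is orange and control siRNA blue, and for each gene both arrays of one group lie above both of the other, as for Ptgds with group means of 346 and 948.

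Further large differences of single genes are given as values. None of them passed over all probe sets by limma without a term for replicate number (adjusted p from 0.248 to 0.353). Their size and order also depend on the constant added to the signal. At the lower end were Cxcl3, a chemokine that attracts neutrophils, with 30.6 ± 19.1 against 278 ± 109 (SD, n = 2 arrays each; log2 -2.67 ± 0.41, SE), and Slc51a, a subunit of a bile acid and steroid transporter, with 349 ± 203 against 1825 ± 839 (-2.38 ± 0.48). Dact2, which modulates Wnt signalling, differed by -2.32 ± 0.53, and Apln, which encodes the peptide hormone apelin, by -2.16 ± 0.43. The cadherin Cdh13 lay at -1.99 ± 0.30, the membrane glycoprotein gene Gpm6b at -1.98 ± 0.18, the ephrin receptor Epha4 at -1.91 ± 0.24 and the semaphorin Sema3d at -1.89 ± 0.44. Ptafr, the receptor of platelet-activating factor, lay at -2.04 ± 0.40, the chemokine Cxcl14 at -1.78 ± 0.29 and Tmem100 at -1.81 ± 0.33. Other probe sets of these genes were also lower with Runx2 siRNA. They lay at -1.75 and -1.74 for Epha4 and -1.44 for Gpm6b, and nearer to 0 at -1.88 and -0.71 for Cxcl3, -0.69 and -0.64 for Cdh13, -0.96 for Apln and -0.92 for a brighter one of Ptafr. Cxcl3, Ptafr, Cdh13, Cxcl14, Epha4, Gpm6b, Dact2 and Rgcc had mean signals of 22.8 to 62.8 with Runx2 siRNA, below the 78.6 used as a limit for dim probe sets. With constants of 1 and 64 in place of 16, the difference was -3.23 and -1.83 for Cxcl3, -2.73 and -1.22 for Ptafr, -2.56 and -1.22 for Cdh13 and -2.11 and -1.23 for Cxcl14. It was -2.17 and -1.39 for Epha4, -2.22 and -1.50 for Gpm6b, -2.63 and -1.75 for Dact2 and -1.13 and -0.68 for Rgcc.

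At the higher end, Cga, the alpha subunit shared by the glycoprotein hormones, had a signal of 241 ± 41.8 against 77.5 ± 3.84 (SD, n = 2 arrays each; log2 1.45 ± 0.21, SE). Fhl2, a LIM domain cofactor of transcription, differed by 1.35 ± 0.27 with a second probe set at 1.27. Adcyap1, which encodes the neuropeptide PACAP, differed by 1.15 ± 0.27 with a second probe set at 0.91, and Tnfaip6, which links hyaluronan in the cumulus matrix, by 1.14 ± 0.26. Tnfaip6 and that second probe set of Adcyap1 are members of the ovulatory list and did not pass in it (adjusted p = 0.0603 for both). Further values were 1.38 ± 0.31 for the keratin Krt33b, 1.32 ± 0.28 for Fcrla, 1.31 ± 0.22 for the retinol dehydrogenase Rdh16, 1.17 ± 0.26 for Stac3 and 1.15 ± 0.26 for the small GTPase Rab30, whose second probe set lay at 0.33. The probe sets of Wwox, an oxidoreductase gene, went in opposite directions, at 1.97 ± 0.26 and -0.98 ± 0.17, the first with a control signal of only 23.7, and those of Btbd2 lay at 1.11 and 0.20. The mean signals of Cga, Rab30, Fcrla, Rdh16, Stac3 and Krt33b with control siRNA, 46.9 to 77.5, were also below 78.6. With constants of 1 and 64 the difference was 1.61 and 1.10 for Cga, 1.32 and 0.83 for Rab30, 1.51 and 0.96 for Fcrla and 1.51 and 0.92 for Rdh16. It was 1.40 and 0.78 for Stac3, 1.66 and 0.91 for Krt33b and 2.52 and 1.21 for the dim probe set of Wwox. In all, 218 probe sets differed at least 2-fold with both arrays of one group above both of the other, 65 higher and 153 lower with Runx2 siRNA. The split was 35 higher and 188 lower after quantile scaling and 30 and 196 after cyclic loess, but 481 and 246 without the filter on dim probe sets, 290 and 263 without the second control array and 306 and 342 without the first Runx2 siRNA array. Dividing the 4 arrays by replicate number instead gave 272 such probe sets, and the remaining division gave 7. Over all sizes the siRNA groups were separated in 47.4% of probe sets, where chance gives 33.3%. The share was 37.7% for the division by number and 14.9% for the remaining division. A probe set without ties is separated in only a single division, so these shares and counts depend on each other. The low values of the remaining division are no independent baseline.

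Cholesterol synthesis genes were lower with Runx2 siRNA in 21 of 22 measured members, and the list fell (median log2 -0.51, adjusted p = 3.5e-07 by camera, n = 2 arrays per group). With an estimated correlation of 0.80, a camera test on 2 residual degrees of freedom, the adjusted p = 0.886 and the unadjusted p = 0.285. No member passed over the list alone. Hsd17b7, which acts in both cholesterol and estradiol synthesis, had a signal of 3064 ± 2123 against 6739 ± 2254 (SD), and Stard4, a sterol carrier, 734 ± 301 against 1449 ± 519. The other Stard4 probe sets went in opposite directions, at -0.78 ± 0.31 and, for the dimmest, 0.60 ± 0.19 (log2, SE). Lanosterol synthase, Lss, differed by -0.93 ± 0.46 and the sterol isomerase Ebp by -0.82 ± 0.34 (log2, SE). The median was -0.47 between the arrays numbered 1 and -0.49 between those numbered 2, but the control arrays also differed from each other, with the second lower by a median of -0.50. Without the second Runx2 siRNA array, the one that stood apart in spike-ins and actin ratio, the median was -0.20, and without the first control array it was -0.25, both still called. Without the first Runx2 siRNA array it was -0.78, and without the second control array -0.76. Each of these fits also holds part of the difference between numbers, which had a median of -0.52 in the Runx2 siRNA pair.

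Cell cycle genes were higher in 33 of 37 measured members and the list rose (median 0.39, adjusted p = 0.000753 by camera). With an estimated correlation of 0.38 the adjusted p = 0.886 and the unadjusted p = 0.360. No member passed over the list alone. Plk1, a mitotic kinase, had a signal of 174 ± 15.8 with Runx2 siRNA and 85.0 ± 39.3 with control siRNA (SD, n = 2 arrays each), and Cdc20, an activator of the anaphase-promoting complex, 252 ± 66.8 and 121 ± 18.7, with a second Cdc20 probe set at a log2 difference of 0.27 ± 0.45 (SE). The list was not called without the second Runx2 siRNA array, which stood apart in spike-ins and actin ratio (median 0.22). Its median was 0.16 without the first control array and 0.62 and 0.60 without the other arrays. These fits also hold part of the difference between numbers. The list was higher in number 2 by medians of 0.28 with Runx2 siRNA and 0.33 with control siRNA.

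Follicular granulosa genes were higher in 20 of 24 members and the list rose (median 0.37, adjusted p = 0.0111), with adjusted p = 0.733 with an estimated correlation. Igf1 rose over the list alone, whereas Wnt4 and Igf1r fell. Cyp19a1, the aromatase that makes estradiol, lay at 663 ± 273 against 1717 ± 752, and Inhbb, an inhibin and activin subunit, at 3159 ± 1222 against 1773 ± 566 (SD, n = 2 arrays each). Luteal genes were lower in 16 of 20 members and the list fell (median -0.24, adjusted p = 0.00753), with adjusted p = 0.733 with an estimated correlation. Scarb1, the receptor that takes up cholesterol from high-density lipoprotein, differed by -0.76 ± 0.24 and the protease inhibitor A2m by -0.71 ± 0.27 (log2, SE), and no member passed over the list alone. The follicular list was not called without the second control array (median 0.29). The luteal list was not called without that second Runx2 siRNA array (median -0.14) or without the first control array (median -0.12). These fits also hold part of the difference between numbers, with luteal medians of -0.28 with Runx2 siRNA and -0.26 with control siRNA.

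Genes of endoplasmic reticulum and amino acid stress were lower in 19 of 25 members and the list fell (median -0.10, adjusted p = 0.00749), with adjusted p = 0.733 with an estimated correlation. Psat1 fell over the list alone. Other members had log2 differences of -0.70 ± 0.26 for the chaperone Hyou1 and -0.59 ± 0.21 for Phgdh, the first enzyme of serine synthesis (SE, n = 2 arrays per group). The median was -0.04 without the second Runx2 siRNA array, -0.06 without the first control array and -0.21 without the second control array.

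The remaining lists were not called by camera over the 4 arrays. Ovulatory genes were higher in 21 of 32 members (median 0.14, adjusted p = 0.290). Among them the hyaluronan synthase Has2 had a log2 difference of 1.15 ± 0.35 and the growth factor Btc 1.03 ± 0.40 (SE, n = 2 arrays per group). The chemokine receptor Cxcr4 lay at -0.95 ± 0.31. Has2 and Btc had control means of 43.9 and 61.4, below 78.6. With constants of 1 and 64 the difference was 1.38 and 0.76 for Has2 and 1.24 and 0.69 for Btc. The ovulatory list was called higher without the second control array (median 0.19), a fit that also holds part of the difference between numbers. Prostaglandin genes had a median of 0.14 (adjusted p = 0.823), with Ptgds past the threshold over the list alone and Ptges and Ptgs2, which act in prostaglandin E2 synthesis, at 0.76 ± 0.20 and 0.76 ± 0.25. Genes of cAMP signalling and the immediate early response had a median of -0.01 (adjusted p = 0.256), from Fosb at the lower end to the nuclear receptor Nr4a3 at 0.78 ± 0.24. The other Nr4a3 probe sets disagreed, at 0.92 ± 0.22 and -0.21 ± 0.23. Matrix and protease genes had a median of 0.03, a mean of -0.11 and the direction down by camera (adjusted p = 0.133). Without the second Runx2 siRNA array the matrix and cAMP lists were called lower (medians -0.18 and -0.02). So they were without the first control array (-0.25 and -0.08). These fits also hold part of the difference between numbers, and the medians of both lists were higher in number 2 with either siRNA. Bone targets of Runx2 had a median of 0.14 and a mean of -0.10 (adjusted p = 0.980), with Mmp13 and Spp1 past the threshold over the list alone. Steroidogenesis genes had a median of -0.09 (adjusted p = 0.256), p53 and apoptosis genes 0.18 (0.319), ribosomal protein genes 0.14 (0.142) and oxidative phosphorylation genes 0.07 (0.510). With each array left out in turn the steroidogenesis median ran from -0.16 to -0.04. It ran from -0.002 to 0.31 for p53 and apoptosis and from 0.01 to 0.11 for oxidative phosphorylation. The ribosomal list was called higher without the first Runx2 siRNA array (median 0.31, adjusted p = 7.3e-08), while its median was -0.03 after quantile scaling and -0.04 without the second Runx2 siRNA array. That of the bone targets was -0.01 after quantile and -0.03 after cyclic loess scaling. Of the p53 genes, Phlda3 differed by 1.22 ± 0.34 and Gadd45a, a growth arrest gene, by -1.10 ± 0.21. When fry tested each list for change in either direction, the follicular (adjusted p = 0.00199), prostaglandin (0.0136) and cAMP lists (0.0188) passed, and in its test for a shift one way no list did (lowest adjusted p = 0.663).

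Markers of other ovarian cells were also measured. Leukocyte markers were higher in 5 of 6 members (median 0.35, adjusted p = 0.290), among them Csf1r, a macrophage receptor, with 106 ± 9.90 against 59.1 ± 7.74 (SD, n = 2 arrays each). Theca and stroma markers had a median of 0.12 (adjusted p = 0.871), endothelial markers 0.10 over 4 members (0.715) and the single oocyte marker tested 0.38 (0.465). With each array left out in turn the median ran from 0.11 to 0.63 for leukocyte, -0.15 to 0.43 for theca and stroma, -0.02 to 0.44 for endothelial and 0.08 to 0.68 for the oocyte marker. After quantile and cyclic loess scaling it was -0.04 and -0.02 for theca and stroma and -0.07 and -0.08 for endothelial markers. Interferon response genes were higher in 26 of 35 members (median 0.18, adjusted p = 0.485), with a median of 0.44 between the arrays numbered 1 and -0.04 between those numbered 2. Isg15, a ubiquitin-like protein induced by interferon, lay at 5003 ± 2301 against 3111 ± 2228. The interferon list was called lower without the first control array (median -0.35). It was called higher without the second control array (0.70) and without the first Runx2 siRNA array (0.46). These fits also hold part of the difference between numbers. The list was higher in number 2 by medians of 0.58 with Runx2 siRNA and 1.02 with control siRNA. These calls therefore cannot be read as effects of the siRNA.

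**Figure D2:**
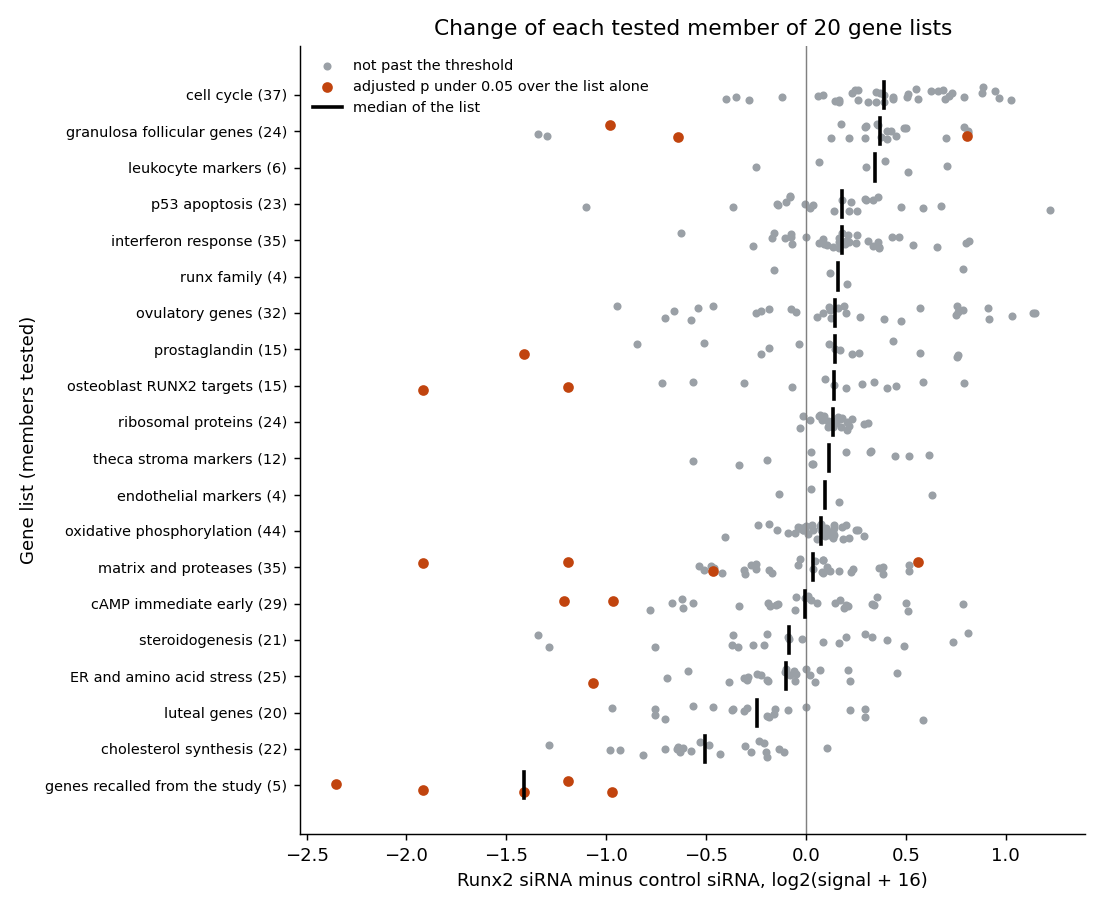
Log2 difference of Runx2 siRNA minus control siRNA on the log2(signal + 16) scale for each tested member of 20 gene lists, 1 point per gene, with a black bar at each list's median and orange points for genes past an adjusted p of 0.05 over the list alone. The cholesterol synthesis median lies at -0.51 and the cell cycle median at 0.39, and the numbers in brackets are the members tested.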

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

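Both signals below lie outside the tested probe sets and are given as values, with the comparison chosen after the arrays had been seen. The spike-in transcripts, 18 control probe sets, had a geometric mean signal of 2478 on the second Runx2 siRNA array, 1.60 times that of the highest control array, against 1372 on the first Runx2 siRNA array. The 5S ribosomal RNA control probe set read 5599 on the second Runx2 siRNA array, 3.39 times the highest control array, against 1890 on the first. No biological explanation was tested for either.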

How the results depend on the processing

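The count at an unadjusted p under 0.05 and the background of 1 probe set per gene were chosen after seeing the data. With 2 arrays per group, or 1 after leaving one out (assumed to vary like the other group), precision is limited, and dim probe sets near the array background depend most on the constant and filter. No probe set passed over all (limma; 2225 at an unadjusted p under 0.05) in any setting but the replicate block, nor at an adjusted p under 0.1. The labels do not say that a replicate number marks a shared culture, and there are only 2 pairs, though deviations of same-numbered arrays correlated at 0.548 across probe sets. With the replicate block, 1512 probe sets passed (610 higher, 902 lower), 4862 had an unadjusted p under 0.05, 152 list memberships passed, among them the original 18 (5 of these in the recalled list), and 61 of 67 named probe sets passed. Without the intensity trend 13 of the 18 list memberships were kept, and Igf1r, Serpine2 and Adamts1 were not called. Leaving out an array gave 871 to 3596 probe sets at an unadjusted p under 0.05, 231 to 648 differing 2-fold and 14 to 83 list memberships. The 2-fold count was 114 with a constant of 64, 727 without the filter and 109 with the lowest 60% left out, where fewer dim probe sets remain. The 6 called lists, the recalled one among them, became 2 with the lowest 60% left out, where the medians of the uncalled lists were -0.19 (luteal), 0.33 (follicular), 0.19 (cell cycle) and -0.10 (stress), and the oocyte list had no tested member. With an estimated correlation 0 lists were called, in a test on 2 residual degrees of freedom that a list can hardly pass after adjustment. Without adjustment the lists called at 0.01 had a camera p from 0.0961 to 0.360 in that test. The medians were unchanged, at -1.41 (recalled), -0.51 (cholesterol), -0.24, 0.37, 0.39 and -0.10. Without the filter the follicular list was not called (0.36). Leaving out an array, medians ranged from -0.31 to -0.12 (luteal), 0.29 to 0.41 (follicular) and 0.16 to 0.62 (cell cycle). The matrix list was called with the mean of probe sets (-0.029, adjusted p = 0.0303), the ribosomal list after cyclic loess (0.10, 0.0263) and the interferon list with the replicate block (0.18, 0.0333). The interferon median ran from -0.35 to 0.70 with an array left out and reversed without the first control array, in fits with unequal numbers between the siRNA groups. Cbfb reversed to -0.013 as the mean of its probe sets, which point opposite ways, and the other 66 named probe sets kept their direction there and all 67 in the settings with all of them tested. Where no construction is named, the cause was not tested. Alternatives for Runx2 itself were not run, since no probe set is named for it here.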

Other observations

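The tests in this part were chosen after the values had been seen, except the list medians with an array left out, which were planned. The arrays that the labels number 2 differed from those numbered 1 in both siRNA groups. In a limma test by number alone 2 probe sets passed. The log2 differences and list tests by number are from a model with siRNA and number, which leaves 1 residual degree of freedom. In that model 1064 probe sets passed, 572 higher and 492 lower in number 2. Its SEs cannot be set beside those of the siRNA differences above, which come from a model without number. Lcn2, an iron-sequestering lipocalin, read 528 and 1730 on the number 2 arrays (Runx2 siRNA, control siRNA) and 32.3 and 38.3 on the number 1 arrays, a log2 difference of 4.25 ± 0.31 (SE, 2 arrays per number). Other differences were 3.67 ± 0.36 for the antimicrobial lectin Reg3g, 3.13 ± 0.36 for the chemokine Ccl20, 3.02 ± 0.12 for the chemokine Cxcl1, 3.04 ± 0.24 for Bcl3 and 2.84 ± 0.14 for Nfkbiz, both regulators of NF-kB, and 2.51 ± 0.18 for the adhesion molecule Vcam1.

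Lhcgr, the receptor of luteinizing hormone, was among the lower genes and read 238 and 547 in number 2 against 1640 and 2524 in number 1, a log2 difference of -2.44 ± 0.13. Scd, a fatty acid desaturase, differed by -2.18 ± 0.22, Snap25, a vesicle fusion protein, by -1.74 ± 0.16 and Hsd17b1, which makes estradiol from estrone, by -1.32 ± 0.10. Fabp6, which had lower values with Runx2 siRNA, was also lower in number 2, by -1.32 ± 0.16. Interferon response genes were higher in number 2 in both siRNA groups for 30 of 35 members (medians 0.58 with Runx2 siRNA and 1.02 with control siRNA; adjusted p = 5.3e-24 by camera, adjusted p = 0.469 with an estimated correlation). Cholesterol synthesis genes were lower in both for 21 of 22 members (medians -0.52 and -0.50; adjusted p = 1.7e-14 by camera, adjusted p = 0.433 with an estimated correlation).

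For this difference between numbers, scaling of the second Runx2 siRNA array is argued against, since the interferon median was 1.02 (interquartile range 0.79 to 1.56) in the control pair, which does not hold that array. Conditions shared by cultures of one number were not tested and stay open. More leukocytes in number 2 stay open, with a leukocyte median of 0.32 in the control pair and 0.33 in the Runx2 siRNA pair over 6 members. Cd14, the brightest of them, read 758 and 956 in number 2 (control siRNA, Runx2 siRNA) and 456 and 633 in number 1. No other biological explanation was tested, as the labels give no group for the numbers.

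For the lower cholesterol synthesis genes with Runx2 siRNA, a distortion that depends on brightness is argued against: 0 of 10000 random lists matched on mean signal had a median as low, a share of 0.01% with 1 added to both numbers, and 95% of them ran from -0.08 to 0.12. An effect of the second Runx2 siRNA array alone cannot be told apart, because the first lay at a median of -0.20 from the control mean while the control arrays lay 0.25 to either side of it. From the control array of its own number the first lay at a median of -0.47, but that sets 1 array against 1. The spread between cultures cannot be told apart either, since the comparisons across numbers gave medians of -0.031 and -1.05. An effect of the Runx2 siRNA, the biological explanation in the design, stays open and may add to a difference between cultures.

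Whether the reported genes respond to interferon was not tested. An interferon response that differed between the siRNAs at both replicate numbers could have produced differences like those reported. This stays open: the median between the siRNAs was -0.037 (interquartile range -0.30 to 0.08) in number 2, with members going both ways, and 0.44 in number 1. The number 2 pair holds the Runx2 siRNA array that stood apart. Without the first and without the second control array the medians were -0.35 and 0.70, but those fits also hold part of the difference between numbers. Off-target effects of the siRNA sequence stay open too, as each group received 1 siRNA treatment.

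Jag1 and Hey2 were lower with Runx2 siRNA but did not pass over all probe sets without a term for replicate number. A hypothesis that they may reflect a shift of the Notch pathway stays open after a test of 8 other members. Their median was 0.22 (camera from limma, adjusted p = 0.713 over both added lists). These went both ways: the target genes Hey1 and Hes1 lay at -0.48 and -0.31, and Notch1, Notch3 and the transcription factor Rbpj at 0.51, 0.37 and 0.24. A like hypothesis for guidance genes came from Epha4, Sema3d and Slit2, which did not pass over all in that fit either. It stays open as well after a test of 34 other members (median 0.11, adjusted p = 0.713 by the same test). These ran from -0.88 for Efnb1 and -0.72 for Sema3b to 0.67 for Sema3e and 0.78 for Epha3.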
